A study of Drosophila melanogaster with 4 samples.

How the data were processed

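RNA was measured by sequencing in ovaries of Drosophila melanogaster from 2 genotypes, with 2 libraries each. The mutant flies carried snf148, an allele of sans fille (snf), which encodes a protein of the U1 and U2 small nuclear ribonucleoproteins. Per the labels, mutant females were 3-day adults, whereas wild-type females were virgins collected 0 to 24 hours after eclosion, so genotype and age differed together. Total RNA was treated with DNase and made into stranded total RNA libraries that were read as paired ends on an Illumina instrument, per the labels' protocols.

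The submitters' processing notes name TopHat2 2.0.9 and Cuffdiff, the latter without a version. The genome build, annotation and counting options are not given in the sources used here. A pair of tables with the authors' own comparison was analysed. Per the file headers, each row gives a gene, its locus, the mean FPKM (fragments scaled to gene length and to the number of mapped fragments) of each genotype, a log2 fold change of wild type over snf148, a P value and an adjusted P value, all computed by the authors. The largest adjusted P value in the authors' deposited table is 0.0497 and the smallest is 0.00126, shared by 466 genes. Genes outside these tables were not analysed here, so the absence of a gene says nothing about its level. No per-library value was analysed here, so the sequencing depth is unknown, no SD or n stands beside a mean FPKM, and the planned limma or edgeR fit of the libraries could not be run.

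Direction was taken from the mean FPKM columns and is given throughout as snf148 relative to wild type. The table titled as downregulated holds 665 genes, all higher in snf148, and the table titled as upregulated holds 618 genes, all lower in snf148. This follows from the authors' fold change being wild type over mutant. For 1242 genes above 0 in both groups, log2 of the ratio of the deposited mean FPKM was recomputed; it differed from the authors' log2 value by more than 0.001 for 5 genes, by at most 0.104. Single-gene folds below are these recomputed ratios, and medians over a table are of the authors' log2 values. A gene listed at 0 in a group got no fold of its own; in the medians of the authors' log2 values over a table or list it ranks beyond all finite ratios, and the tests of log2 ratios leave it out.

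Loci are given as in the deposited tables, with starts moved to count from 1. Starts counted from 0 matched the reference gene length for 439 genes and starts counted from 1 for 7. The build is not named and differs from release 6 of the reference, so that annotation was used only for gene names, which matched for 1265 of the 1283 genes, and for the order of neighbouring genes.

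The following choices were made before the data were examined: 30 gene lists, the tests and the rule for named genes. Each list with at least 3 listed members was tested with a two-sided Fisher's exact test of members against non-members, higher against lower, over the 1283 listed genes, with Benjamini-Hochberg adjustment over the 22 lists tested and a threshold of 0.05. Such a test asks whether listed members lean to one side more than the other listed genes do. Lists with 3 or 4 listed members could not pass in any split. With 4 members all higher the unadjusted Fisher p is 0.125, and with 4 all lower it is 0.0536. With 7 all higher it is 0.0158, or 0.0631 after adjustment. Lists of up to 7 listed members could therefore not pass with all members higher. The test is no enrichment against all expressed genes. Because only genes past the authors' threshold are at hand, no count adjusted over the list alone can be given. Fisher's exact test was also used for genes at 0 and for X linkage, with 95% Wilson intervals for shares. Medians of gene span and level were compared by two-sided permutation tests, and pairs of listed genes starting within 10 kb of each other by a one-sided permutation of direction, each with 100000 resamples. Genes are not independent replicates, and none of these p-values measures variation between flies.

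Named genes were snf, Sxl and Phf7 where listed, the 8 largest and 8 smallest log2 ratios among genes of at least 1 FPKM in the higher group, the 5 genes at 0 in one group with the highest level in the other, and up to 4 members of each list per direction with the highest FPKM. Other members of the fixed lists, and genes of lists added later, were chosen after their values were seen. The alternatives were an adjusted P value of at most 0.01, at least 4-fold with genes at 0 in one group kept, at least 1 FPKM in the higher group, genes at 0 left out, pseudocounts of 1 and 0.1 FPKM, a low level of 0.1 FPKM in place of 0, repeated names counted once, unnamed genes left out, and distances of 5 and 20 kb. Leaving out 10 genes with shared loci or on unplaced sequence was added later. Near-identical copies such as Hsp70Bb and Hsp70Bc, or Sdic1 and Sdic3, share reads and their values are uncertain.

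The tests were tested on simulated data with 1283 genes. Of random lists with 12 listed genes, 3.50% were called, against 92.0% of lists with a strong lean. These calls used the unadjusted Fisher p, and most tested lists had fewer than 12 members. The 92.0% therefore overstates what the adjusted test can find. For the median test 6 of 100 unshifted simulations were called, and for the neighbour test 7 of 100 random directions, against 100 of 100 with an effect in each. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.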

Results

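Ovarian RNA of snf148 mutant females was compared with that of wild-type females, with 2 libraries per genotype. The product of snf is needed for correct splicing of Sex-lethal (Sxl) RNA, and the germ cells of snf148 females fail to accumulate Sxl protein and form tumours. The comparison addressed which transcripts differ in such ovaries. Unless stated otherwise, a pair of values is the authors' mean FPKM, snf148 first and wild type after it; these means carry no replicate error and the depth behind them is unknown. The mutant females were 3-day adults and the wild-type females 0 to 24 hours old, so every difference below is one of genotype and age together. The wild-type females were also labelled as virgins, so mating status may differ as well.

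Among the genes in the authors' tables, 19 of 21 listed spermatid and late spermatocyte products were higher in snf148 ovaries, and all 15 listed genes of oocyte patterning and all 12 of the cell cycle were lower. The spermatid list also holds genes expressed in the ovary, such as cher and RpS19b. RpL37b, a ribosomal protein paralogue, stood at 85.1 against 0.661 FPKM, a 129-fold ratio, and eIF4E-3, a translation initiation factor of spermatocytes, at 45.6 against 0.443 FPKM. Oskar (osk), which organises the germ plasm at the posterior pole of the oocyte, stood at 248 against 967 FPKM. All 15 listed heat shock and stress genes were higher, among them Hsp68 at 589 against 60.3 FPKM. The chorion gene Cp18 stood at 5.98 against 251 FPKM, although the eggshell list as a whole did not pass its test.

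In all, 665 genes were listed as higher and 618 as lower. The median log2 fold change in the authors' deposited table was 2.37 for higher genes (95% interval of the median over genes 2.24 to 2.50; 2.26 over the 626 genes above 0 in both groups) and -1.07 for lower genes (-1.1250 to -1.0002). At least 4-fold differences made up 387 higher genes, or 58.2%, and 128 lower genes, or 20.7%, with genes at 0 in one group counted among them; without these the counts were 348 and 126. Higher genes were expressed at lower levels: the median FPKM in the group with the higher value was 14.1 for higher genes and 63.5 for lower genes (permutation p = 1e-05, the smallest that 100000 resamples can give). With at least 4-fold required the medians were 4.45 and 9.41 FPKM (permutation p = 0.00073). At low levels only large ratios appear in the tables, so the medians of the 2 directions are not comparable as effect sizes.

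**Figure D1:**
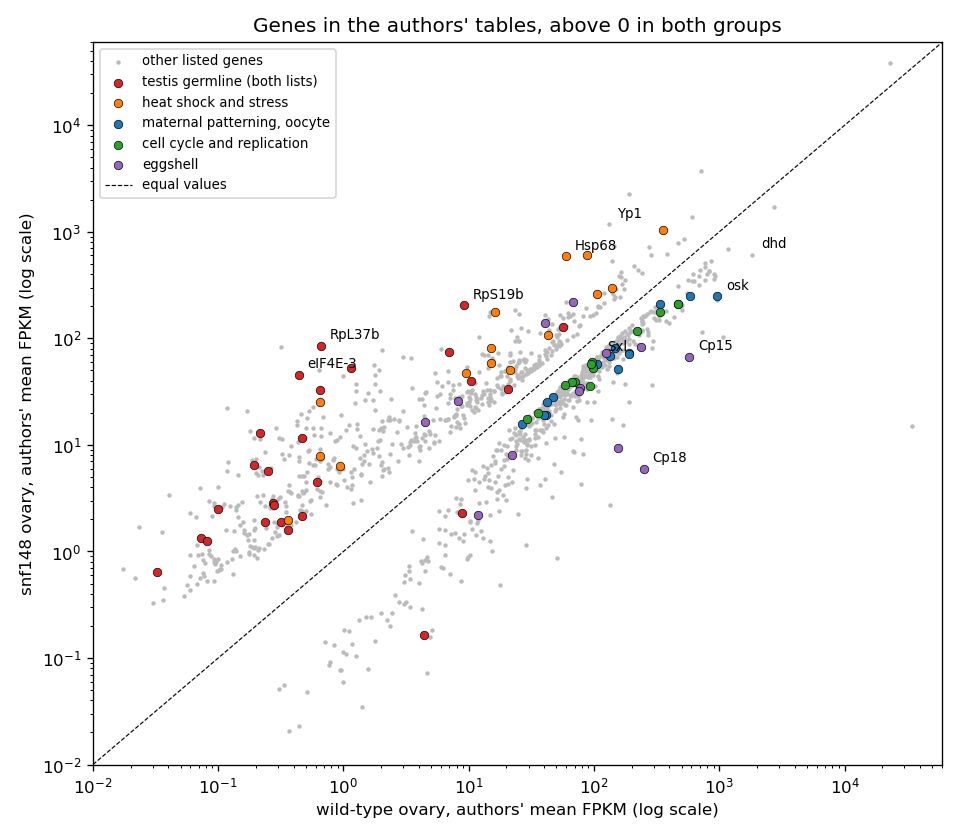
Authors' mean FPKM in snf148 ovaries (y axis, log scale) against wild-type ovaries (x axis, log scale) for 1242 listed genes above 0 in both groups; each point is a gene, colours mark gene lists and the dashed line marks equal values. Testis germline list members such as RpL37b lie far above the line, and osk, Cp18 and the testis list members scpr-A and scpr-C lie below it.

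Of the genes that motivated the rule for naming, Sxl was listed as lower, at 66.6 against 110 FPKM, a log2 ratio of -0.72; the authors' deposited table gives it an adjusted P value of 0.0140. Its locus runs from 6968583 to 6992089 on chromosome X in the build of the tables, which is not named. A gene-level FPKM does not separate the male and female splice forms of Sxl. The mutated gene snf and Phf7, a chromatin reader of the male germline, are not among the listed genes, so the mutation could not be checked from RNA level. Sxl was the only listed gene among 19 of the sex determination and dosage list.

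Of the 124 spermatid and late spermatocyte products on the list, 21 were in the tables, 19 higher and 2 lower (adjusted Fisher p = 0.00130). The median log2 fold change of the higher members in the authors' deposited table was 3.93, or 3.42 over the 17 members above 0 in both groups. RpS19b, a ribosomal protein paralogue also used in early female germ cells, stood at 204 against 9.24 FPKM. RpL22-like reached 53.2 against 1.15 FPKM and RpS10a 73.9 against 6.93 FPKM. The filamin gene cher, which is also expressed in ovarian ring canals and follicle cells, stood at 127 against 57.0 FPKM. The lower members were scpr-A and scpr-C, the latter at 2.28 against 8.79 FPKM. RpL37b lies at 18987580 to 18987982 on 2R, and eIF4E-3 at 8222324 to 8223668 on 3L.

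All 7 listed regulators of the testis transcription programme, of 26 on the list, were higher, although this list missed the threshold (adjusted Fisher p = 0.0631). With 7 listed members it could not lean further to the higher side, so no higher lean could have passed. Taf12L, which encodes a TAF of the testis TFIID, stood at 32.9 against 0.646 FPKM. Rbp4, an RNA-binding protein of spermatocytes, stood at 12.9 against 0.214 FPKM, and CG13597, now named tbrd-1, at 6.50 against 0.192 FPKM. The meiotic arrest genes aly and can stood lower on the scale, at 2.73 against 0.278 and 0.635 against 0.0324 FPKM. Of the 26 higher genes of both testis lists, 20 were below 1 FPKM in wild type and 6 were not, and 11 reached at least 10 FPKM in snf148. With only differences of at least 4-fold counted, 16 spermatid products were higher, 2 of them listed at 0 in wild type, and 1 was lower. The adjusted Fisher p rose to 0.307. Most genes at that fold are higher, 387 against 128 lower, and fewer list members remain, and these influences were not separated.

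All 15 listed genes of maternal patterning and oocyte determination, of 41 on the list, were lower (adjusted Fisher p = 0.000351), with a median log2 fold change of -1.06 in the authors' deposited table. The Bruno gene, listed as aret, stood at 252 against 580 FPKM. The polar granule component pgc stood at 73.1 against 191 FPKM, and orb, which regulates translation of oocyte messages, at 71.9 against 191 FPKM. BicC stood at 51.7 against 155 FPKM and gurken (grk) at 18.9 against 41.4 FPKM. No member reached 4-fold, so the list cannot be tested at that minimum. The osk locus runs from 4760001 to 4764117 on 3R.

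Cell cycle and replication genes, of which 12 of 40 were in the tables, were lower in all 12 cases (adjusted Fisher p = 0.00108), by a median of -0.86 on the log2 scale in the authors' deposited table. The cyclin genes CycB and CycA stood at 212 against 466 and 177 against 337 FPKM, and the ribonucleotide reductase gene RnrL at 57.5 against 94.5 FPKM. The phosphatase gene string (stg) stood at 35.8 against 93.7 FPKM. CycB belongs to the maternal list as well. No member of this list reached 4-fold either.

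All 15 listed genes of the heat shock and stress response, of 38 on the list, were higher (adjusted Fisher p = 0.000709), with a median log2 fold change of 2.45 in the authors' deposited table. The small heat shock gene Hsp26 reached 1036 against 355 FPKM and Hsp23 609 against 88.0 FPKM. The co-chaperone gene DnaJ-1 stood at 298 against 139 FPKM. Hsp70Bc stood at 25.5 against 0.644 FPKM, but its reads are shared with near-identical copies. With at least 4-fold required, 9 members were higher and 0 lower, with an adjusted Fisher p of 0.347. Of all genes at that fold, 387 were higher and 128 lower. With 9 members the list could not lean further to the higher side, so no higher lean could have passed there.

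**Figure D2:**
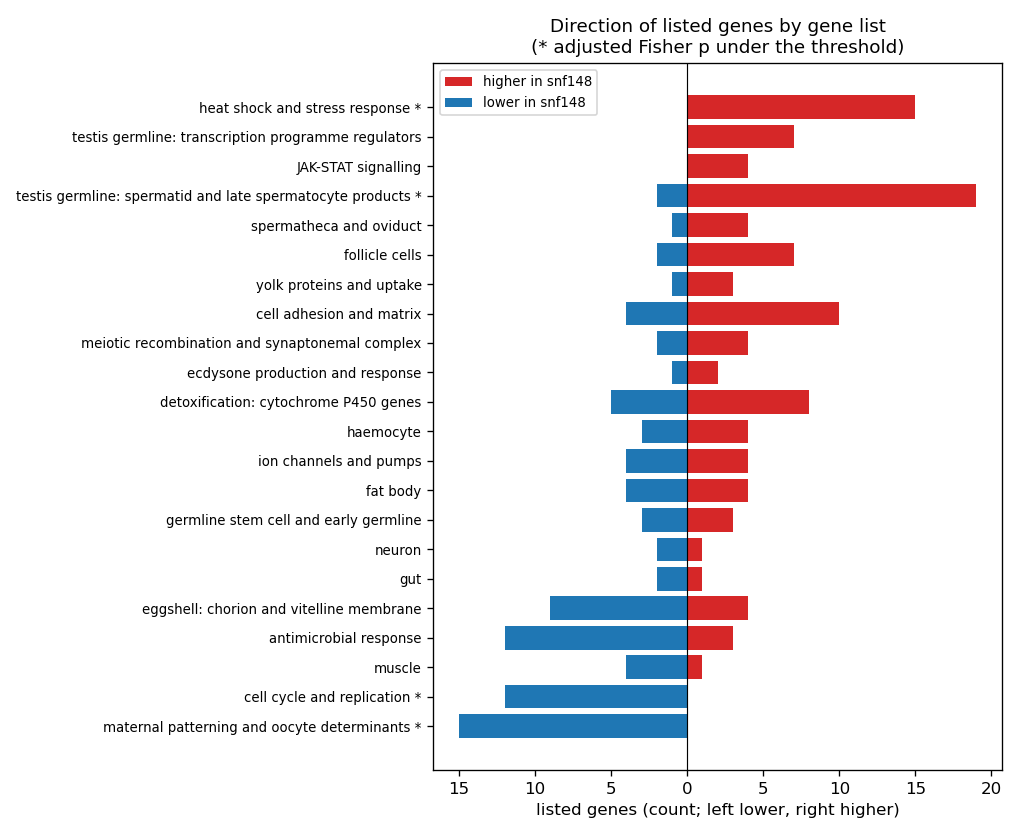
Number of listed genes higher (right, red) and lower (left, blue) in snf148 ovaries for each of the 22 tested gene lists; the x axis counts genes and asterisks mark the 4 lists past the threshold. Maternal patterning and cell cycle bars lie entirely on the lower side, with 15 and 12 genes, and heat shock entirely on the higher side, with 15.

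Eggshell genes went both ways, with 4 higher and 9 lower (adjusted Fisher p = 0.399). The vitelline membrane gene Vm26Aa stood at 219 against 67.9 FPKM and dec-1 at 138 against 40.9 FPKM, whereas fs(1)M3 and fs(1)N, also of the vitelline membrane, stood at 34.2 against 77.5 and 32.3 against 75.9 FPKM. The listed chorion genes Cp15, Cp16, Cp18 and Cp19 were lower, with Cp15 at 67.2 against 578, Cp16 at 9.42 against 154 and Cp19 at 83.5 against 235 FPKM, as was yellow-g2 at 2.20 against 11.8 FPKM. With at least 4-fold required, 0 eggshell genes were higher and 4 lower (adjusted Fisher p = 0.0331). The yolk protein genes Yp1, Yp2 and Yp3 stood at 1173 against 131, 729 against 145 and 534 against 140 FPKM, whereas the yolk receptor gene yl stood at 160 against 435 FPKM. The yolk list had 3 higher and 1 lower (adjusted Fisher p = 0.860), but a list with 4 listed genes could not pass the test in any split.

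Among somatic and early germline lists, none passed the threshold. Follicle cell genes were listed 7 times as higher and 2 times as lower (adjusted Fisher p = 0.399), with Fas3, an adhesion protein of polar and early follicle cells, at 165 against 53.2 FPKM and cas at 11.7 against 3.74 FPKM. All 4 listed genes of JAK-STAT signalling were higher (adjusted Fisher p = 0.394), too few to pass in any split. The ligand genes upd2 and upd3 stood at 2.67 against 0.0919 and 6.39 against 0.934 FPKM. Cell adhesion and matrix genes were split 10 to 4 (adjusted Fisher p = 0.399). Early germline genes were split 3 to 3 (adjusted Fisher p = 1), with bgcn, a partner of bam in germline differentiation, at 21.1 against 1.78 FPKM. Genes of meiotic recombination were split 4 to 2 (adjusted Fisher p = 0.890), with the cohesion gene ord at 26.5 against 1.72 FPKM and mtrm at 76.1 against 161 FPKM.

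Markers of tissues outside the ovary were also listed. Antimicrobial genes were listed 3 times as higher and 12 times as lower (adjusted Fisher p = 0.0631); IM3 stood at 103 against 1076 FPKM and Drosomycin (Drs) at 80.4 against 288 FPKM, whereas Tep4 stood at 167 against 40.4 FPKM. With at least 4-fold required, 3 antimicrobial genes were higher and 8 lower, 1 of these listed at 0 in snf148 (adjusted Fisher p = 0.0180). Muscle genes had 1 higher and 4 lower (adjusted Fisher p = 0.404), with Act79B at 1.02 against 15.4 FPKM. Fat body genes were split 4 to 4 (adjusted Fisher p = 1): Rfabg, the lipophorin gene, stood at 59.8 against 25.3 FPKM and Lsp1gamma at 39.0 against 141 FPKM. Haemocyte genes were split 4 to 3 (adjusted Fisher p = 1). Genes of the spermatheca and oviduct had 4 higher and 1 lower (adjusted Fisher p = 0.689), with Send1 at 44.6 against 0.985 FPKM. Gut and neuron genes had 1 higher and 2 lower each (adjusted Fisher p = 0.860 for both).

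For the remaining tested lists, cytochrome P450 genes had 8 higher and 5 lower (adjusted Fisher p = 0.860), ecdysone genes 2 higher and 1 lower, and ion channels and pumps 4 higher and 4 lower (adjusted Fisher p = 1 for both). Cyp6a17 stood at 30.5 against 1.57 FPKM and Cyp6a2 at 1.15 against 28.5 FPKM. Lists with fewer than 3 listed members were not tested: the niche genes esg and dally were higher, Dl of the Notch list was lower, and the splicing genes B52 and hoip were lower. Of the germline histone list, HP1D3csd was higher and His2Av lower. No gene was listed from the piRNA, BMP or male accessory gland lists, which says nothing about their levels.

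The largest ratios outside the lists were those of CG34434, at 83.4 against 0.318 FPKM, and of the noncoding CR40469, at 15.0 against 34744 FPKM. CG34434 lies at 5508587 to 5510403 and CR40469 at 18880 to 19093, both on X. Genes listed at 0 in one group were 39 of the 665 higher genes, at 0 in wild type, and 2 of the 618 lower genes, at 0 in snf148 (5.86% and 0.324%, Fisher p = 1.74e-09). Among genes of at least 1 FPKM in the higher group these were 8 of 590 and 1 of 604 (1.36% and 0.166%, Fisher p = 0.0197), and with values under 0.1 FPKM counted in place of 0 they were 86 and 15 (12.9% and 2.43%, Fisher p = 4.88e-13). The higher genes at 0 were weakly expressed, with a median of 0.509 FPKM in snf148, and 31 of them were below 1 FPKM. Among the strongest of them were the gustatory receptor gene Gr98b at 3.55 FPKM and the testis list member CG7211 at 2.56 FPKM. The lower ones were the immune gene IM14, at 47.0 FPKM in wild type, and Edg91 at 0.226 FPKM.

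X-linked genes made up 152 of 662 placed higher genes, or 22.96% (95% Wilson interval 19.9 to 26.3), and 79 of 617 lower genes, or 12.8% (10.4 to 15.7), a difference with a Fisher p of 2.13e-06. With at least 4-fold required the shares were 23.8% and 7.03% (Fisher p = 1.66e-05). Few of the X-linked higher genes belonged to the testis lists, 3 of 152. The lists held only 26 of all 665 higher genes, so these counts say little about testis expression among X-linked genes. Listed genes close to each other tended to share direction: of 277 pairs starting within 10 kb, 78 were both higher and 102 both lower, so 65.0% shared direction against 50.03% on average after permutation (one-sided permutation p = 1e-05, the smallest possible here). The share depended on distance, with 72.7% within 5 kb (permutation p = 1e-05) and 58.1% within 20 kb (permutation p = 0.00067); at an adjusted P value of at most 0.01 it was 73.5% against 50.4% after permutation (permutation p = 3e-05). The lower chorion genes Cp18, Cp15, Cp19 and Cp16 lie between 8719891 and 8725699 on 3L, and the higher heat shock genes Hsp67Bc, Hsp26, Hsp67Ba, Hsp23 and Hsp27 between 9364611 and 9378382 on the same arm. Gene span did not differ detectably, with medians of 3536 and 3462 bp (permutation p = 0.728).

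**Figure D3:**
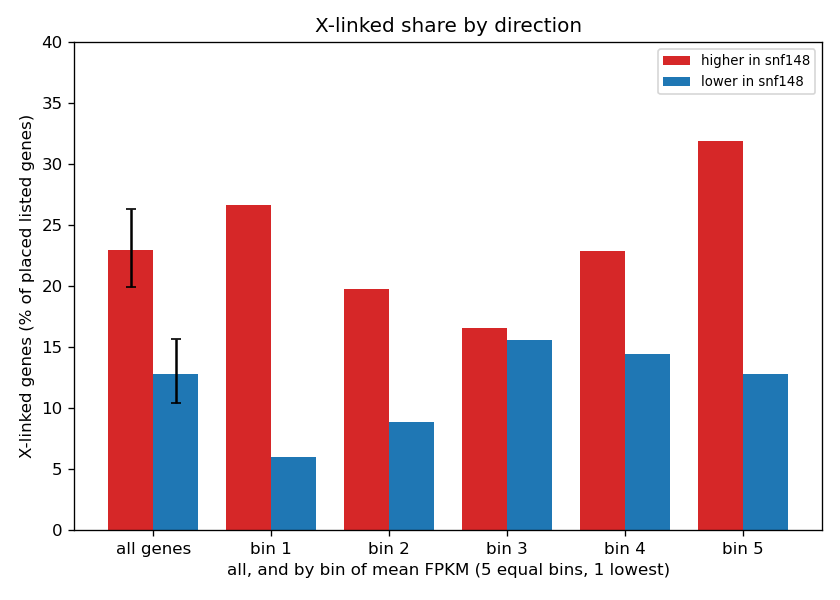
Share of X-linked genes (y axis, percent of placed listed genes) among genes higher (red) and lower (blue) in snf148 ovaries, for all genes with 95% Wilson intervals and for each of 5 equal bins of mean FPKM without intervals. Over all genes the bars stand at 22.96% and 12.8%, and within each of the 5 bins the red bar is the taller one, least so in the middle bin at 16.5% and 15.6%.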

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

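Leaving out genes with shared or unplaced loci was the alternative chosen after the data were seen. Of the alternative values of the comparisons, 38 kept their direction and their side of the threshold or stayed near the main value, 9 moved and 1 changed sign. Of the log2 ratios of named genes with a pseudocount, 207 stayed near the main value and 53 moved. An adjusted P value of at most 0.01 left 423 higher and 348 lower genes, and at least 4-fold left 387 and 128; both follow from fewer genes being counted. The median log2 ratio of higher genes was 1.30 with a pseudocount of 1, 2.05 with 0.1, and 2.14 for genes of at least 1 FPKM; that of lower genes was -0.98 with a pseudocount of 1. Pseudocounts shrink ratios of weakly expressed genes by construction. At least 4-fold gave 2 lists past the threshold, antimicrobial and eggshell genes, and 0 of the 4 lists called in the main test. Spermatid products and heat shock genes missed it, the latter with 9 higher and 0 lower, which could not lean further higher. The other 2, maternal patterning and cell cycle, had no member at 4-fold. The other list alternatives called the same 4 lists. The log2 difference in gene span changed sign to -0.051 at an adjusted P value of at most 0.01 (permutation p = 0.837); neither value passed a test and the cause was not tested.

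Of the log2 odds ratios of the lists, 109 kept their sign and side of the threshold. Another 15, in lists without a call, changed sign, and the cause was not tested except where unchanged counts are given below. With at least 4-fold these were P450 and haemocyte genes at -0.37 each, ecdysone and meiotic genes at -0.0037 each, and early germline genes at 0.74. The lists with negative values still had more higher than lower members, 3 to 1 for P450 and haemocyte genes and 1 to 0 for ecdysone and meiotic genes. All genes at that fold were 387 higher and 128 lower. With an adjusted P value of at most 0.01 the sign changes were fat body at 0.21, ion channels at 0.57 and spermatheca at -0.28. With at least 1 FPKM they were fat body and early germline at 0.034 each and ion channels at 0.40. With unnamed genes left out they were fat body, early germline and ion channels at 0.063 each, and with shared or unplaced loci left out ion channels at 0.25. Fat body and early germline genes kept 4 to 4 and 3 to 3 at 1 FPKM and with unnamed genes left out. Ion channels kept 4 to 4 with unnamed genes left out. In these cases only the other listed genes changed, at 1 FPKM from 665 higher and 618 lower in all to 590 and 604. At 4-fold antimicrobial and eggshell genes had 3 higher and 8 lower (adjusted Fisher p = 0.0180) and 0 higher and 4 lower (adjusted Fisher p = 0.0331).

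No paired analysis was possible because the replicate numbers shared by the groups have no values of their own in the tables, which hold group means. For the same reason leaving out each library, the replicate block and the per-library pseudocount were not run. Depth is unknown, so the precision of weakly expressed genes cannot be given.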

Other observations

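The gene lists in the next paragraph, the test of testis against follicle cell folds, the test across cell types, the test of early germline genes and the test of direction next to snf were chosen only after the result was seen.

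All gene lists in this paragraph were drawn up with the tables in view, so Fisher tests of their direction, run for 7 of the 8 lists, are no independent evidence and the counts stand as descriptions. Genes of the nucleolus and ribosome biogenesis were lower in all 34 listed cases. The small nucleolar RNP genes Nop56 and Fib stood at 211 against 455 and 120 against 240 FPKM, and RpI135, a subunit of RNA polymerase I, at 36.6 against 67.3 FPKM. Purine synthesis genes were lower in all 9 listed cases, with ade3 at 47.7 against 152 FPKM. Of cuticular protein genes of the Cpr family, 7 were higher and 0 lower, with Cpr49Ae at 66.3 against 2.99 FPKM, and of septate junction genes 8 were higher and 0 lower, with Nrg at 109 against 49.3 FPKM. The metallothionein gene MtnA stood at 1369 against 603 FPKM, whereas MtnB, MtnC, MtnD and MtnE were lower, with MtnC at 8.79 against 67.8 FPKM. Tanning genes had 1 higher and 4 lower, with ple at 4.16 against 36.7 FPKM, and phototransduction genes 0 higher and 4 lower, with ninaD at 4.26 against 79.1 FPKM. Thioredoxin genes had 1 higher and 1 lower.

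Most listed testis germline genes were higher in snf148 ovaries, and a smaller share of maturing germ cells could raise all other transcripts alike. Markers of 6 other cell types with a mean of at least 1 FPKM were not all raised, with 19 higher and 16 lower. Medians ran from -2.46 for gut to 4.26 for spermatheca and oviduct, and follicle cells had 7 higher and 2 lower. An equal rise of all other transcripts leaves no room for lower markers. Of the 16 lower ones, 2 were of follicle cells, too few to decide beside 7 higher. The rest were of fat body, gut, muscle, haemocytes, and spermatheca and oviduct. How much of those tissues the samples held is unknown, so their markers cannot decide the question for the ovary. The types did not differ by more than the spread within them (Kruskal-Wallis statistic 8.47, permutation p = 0.122). Such a result does not show a shared rise. A smaller share of maturing germ cells as a part of the cause stays open. Among listed genes of at least 1 FPKM in wild type, 8 testis genes ranged from -4.74 to 5.53 on the log2 scale and 9 follicle cell genes from -1.25 to 1.64, with medians of 1.54 and 0.88 (exact permutation p = 0.185). That minimum left out 20 of the 26 higher testis genes and kept both lower ones, so the comparison cannot speak for the testis genes as a set. More early germ cells of the kind that wild-type ovaries also hold may contribute and cannot be told apart. The 4 early germline and meiosis genes below 10 FPKM in wild type had a median of 2.93. It was 4.18 for 23 testis genes below that level, of either direction and above 0 in both groups (difference -1.25, exact permutation p = 0.214). The comparison cannot decide, since the 4 genes are few and the limit favours genes that rose. The early germline and meiotic lists were split 3 to 3 and 4 to 2, and all their lower genes fell outside the limit. The age difference stays open as untested, and the mutation itself remains a hypothesis.

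X-linked genes had a larger share among higher than among lower genes. No share over all expressed genes is at hand, so an excess among higher genes and a shortage among lower ones cannot be told apart. The difference could reflect the different expression levels of the higher and lower tables. Within 5 equal bins of mean FPKM it was still there, with a Mantel-Haenszel log2 odds ratio of 1.13 (permutation p = 1e-05, the smallest possible here), which argues against level as the whole cause. A small shared upward shift of X-linked genes, as a change in dosage compensation might give, was predicted to put X-linked ratios below autosomal ones among higher genes. The prediction need not hold, since a shift also raises X-linked genes already past the authors' threshold. The median of 138 X-linked genes was 0.10 above that of 485 autosomal genes on the log2 scale (permutation p = 0.535). The difference is within its spread, and genes selected by a threshold cannot decide the question, so a shift stays open. Age and differences carried by the mutant X chromosome were not tested.

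In the release 6 gene order, TrxT and dhd, a pair of thioredoxin genes, follow snf directly, and CG15930 is the fourth gene on that side. TrxT, which is expressed in testis, stood at 22.5 against 0.567 FPKM, dhd, which is expressed in the female germline, at 605 against 1841 FPKM, and CG15930 at 78.9 against 5.98 FPKM. A single regional effect of the mutant chromosome could move neighbours one way; the 3 listed genes took 2 directions, but they are too few to decide, and such an effect on TrxT and CG15930 alone stays open. For the number of listed genes alone chance placement may suffice: 182 of 2186 positions on X, or 8.33%, had at least as many listed genes among the 5 genes on each side. That count ignores that the 3 genes lie on the same side of snf, and it ignores the size of their ratios, so it cannot speak for these.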
